A study of Arabidopsis thaliana and Arabidopsis thaliana x Arabidopsis arenosa and Arabidopsis arenosa with 18 samples.

How the data were processed

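Messenger RNA was sequenced from hybrid and control crosses of Arabidopsis, collected 3 days after pollination. Mothers were A. thaliana of the accessions Col-0 (Col below) or C24, which carried a male-sterility construct and were pollinated by hand. Fathers were of the same accession in the control crosses and a diploid A. arenosa in the hybrid crosses. A further control came from A. arenosa crossed with A. arenosa. Per the labels' protocols, total RNA was treated with DNase I, selected for poly-A tails, fragmented with an enzyme, copied into cDNA with random primers and made into Illumina libraries by the laboratory's own method. No strand marking was stated. The labels name 18 sample records in 9 groups.

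The authors deposited whole-number read counts per gene for 14 libraries in 7 groups of 2, and read counts per transposable element (TE) for the 8 seed libraries of the A. thaliana controls and the hybrids. Per the file headers, each of the 4 A. thaliana control columns is the sum of 2 records of the same cross and number, of which the title of 1 ends in the word single. What that word means was not given in the sources used here. Per the submitters' processing notes, BWA and TAIR10 were used. The version of BWA, the counting rule, the strand setting and the treatment of reads with several matches were not given in the sources used here. Reads of A. arenosa origin were therefore counted on the A. thaliana genome, and reads of a gene and of an antisense or near-identical partner cannot be separated. The deposited counts were not normalised. The gene table held 33602 loci and the TE table held 31189, and 0 value columns were left unmapped to a sample. Libraries are called by group and replicate number below, so that Col control 1 is replicate 1 of the Col control.

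The plan, fixed before the data were examined, assumed that the control columns would hold unsummed records. Since they held sums, each sum was used as 1 library, and alternatives built on the records titled single could not be run. Replicates of a pair differed by far more than sampling noise, so none was counted as a duplicate. The labels do not say that replicates came from separate plants or pools, so p-values measure only the spread between these samples, which may be technical.

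Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Libraries were scaled with TMM factors, low genes were removed by filterByExpr with the groups, and each group had its own mean in a quasi-likelihood fit (glmQLFit, glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Comparisons among the 4 seed groups with an A. thaliana mother shared a fit over 20552 genes. Comparisons with the A. arenosa control used a fit of 5 seed groups over 21619 genes, and those with whole siliques used a fit of the 4 hybrid groups over 20700 genes. TEs were tested the same way over 1421 loci, with library sizes and TMM factors taken from the gene table. The interaction is the hybrid effect in Col minus that in C24. A gene was beyond both parents when it was called in the same direction against the maternal-line control and the A. arenosa control. Standard errors (SE) of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the test's F value. Levels are given as mean CPM (read counts scaled to a common library size) ± SD of the 2 libraries of a group, scaled with the TMM factors of the fit.

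Depth ranged from 1777781 gene reads in A. arenosa control 1 to 16149496 in Col hybrid 1. Where a group had no read, the fold was computed as a bound, with 3 reads per library taken as the floor. Where a group had 1 to 3 reads, the ratio is given with an exact 95% interval from the binomial distribution of the summed counts. Bounds and intervals cover counting error only. Fitted folds of such genes depend on the prior count, so list medians were also computed with these genes at their bound.

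Genes were named from the TAIR10.1 annotation by locus, which matched 32835 loci. No coordinates are given, because this assembly is not the build the authors used. Of the 32827 genes with an exon model (97.7% of the table), 6926 had over 5% of their 31-base exon words elsewhere in the genome. Named genes of this kind are called not unique, with the percent, and their values are uncertain.

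Lists of 279 genes in 16 groups were written from textbook knowledge before the data were examined: type I MADS-box, imprinted and FIS-PRC2, endosperm growth, embryo, seed coat and flavonoid, WRKY, salicylate and immune, jasmonate and ethylene, heat and abiotic stress, cell cycle, DNA methylation and RNA silencing, seed storage, photosynthesis, fruit valve, pollen, and egg cell and synergid genes. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. The list tests of the control, A. arenosa and silique-to-silique comparisons were not in that plan. The rule for named genes took the 8 highest and 8 lowest log2 fold changes per comparison among the 4 seed groups, and the 4 highest and 4 lowest elsewhere. It asked for an adjusted p under 0.05, a mean of at least 5 CPM (1 CPM for TEs) and, except in the interaction, no overlap of replicates. It added up to 4 members of each list with the smallest adjusted p. Other genes singled out are said to have been chosen after their values were seen.

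The scripts were tested on simulated counts for 19988 genes, with 100 genes changed 2-fold and 100 changed 4-fold. Changed genes and list members were taken from genes with a mean of at least 5 CPM, and each gene was drawn independently. For Col hybrid against Col control, 55% and 97% of these were recovered, with 2 false calls. For Col against C24 hybrids, 56% and 95% were recovered, with 8 false calls. For the interaction, 16% and 83% were recovered, with 3 false calls. For Col hybrid against Col control, camera recovered a raised list of 20 genes, and 4 of 100 unchanged lists passed at 0.05.

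Alternatives were other scalings (the size factors of DESeq2, called RLE, and upper quartile), no filter, a minimum of 5 CPM, DESeq2 1.42.0, a fit over all 7 groups, a fit of the compared groups only, a replicate block, and each library left out in turn. Further alternatives were chosen after seeing the data: genes with unique sequence only, and leaving out replicate 1 of both A. thaliana controls, which held more reads than replicate 2 of the same control at genes without a read in any silique library. When a group is left with 1 library, that library is assumed to vary like the other groups. Permuting samples was not informative, since with 2 libraries per group an exact 2-sided test cannot go below p = 0.33. Other calculations and the figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.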

Results

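Transcripts were counted in seeds of hybrid and control crosses 3 days after pollination. The series set the hybrid of a Col-0 (Col) mother with an A. arenosa father, described as incompatible, and that of a C24 mother, described as compatible, against control crosses. Col and C24 are natural accessions of A. thaliana, and A. arenosa is a related species. Each of the 7 groups held 2 libraries: Col, C24 and A. arenosa control seeds, Col and C24 hybrid seeds, and whole siliques, the fruits that hold the seeds, of both hybrid crosses. Gene reads came to 15462720 and 15375118 in Col control 1 and 2, and to 15363061 and 15915323 in C24 control 1 and 2. Col hybrid 1 and 2 had 16149496 and 8931520 gene reads, C24 hybrid 1 and 2 had 12563500 and 11535647, and A. arenosa control 1 and 2 had 1777781 and 2089616. Col hybrid silique 1 and 2 had 13044380 and 14694606, and C24 hybrid silique 1 and 2 had 14346377 and 12448931. A count of 3 reads corresponded to between 0.186 and 0.336 CPM in these libraries, except in A. arenosa control 1 and 2, where it corresponded to 1.687 and 1.436 CPM. Levels below are mean CPM ± SD of the 2 libraries of a group, fold changes are log2 ± SE, and adjusted p-values of genes come from edgeR's quasi-likelihood test.

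Replicates of the A. thaliana controls differed in how many loci had reads. In Col control 1, 31430 genes had at least 1 read, against 23123 in Col control 2, and in C24 control 1 and 2 the numbers were 28243 and 23105. Transposable elements (TEs) took 1.215% of the gene and TE reads of Col control 1 and 0.056% of those of Col control 2. Ribosomal RNA loci took 2.04 and 1.44% of the gene reads of Col hybrid 1 and 2 and 2.11 and 1.79% of those of C24 hybrid 1 and 2. In the Col controls this share was 0.58 and 0.43%, in the C24 controls 0.34 and 0.77%, and in A. arenosa control 1 and 2 it was 3.26 and 2.4%.

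**Figure D1:**
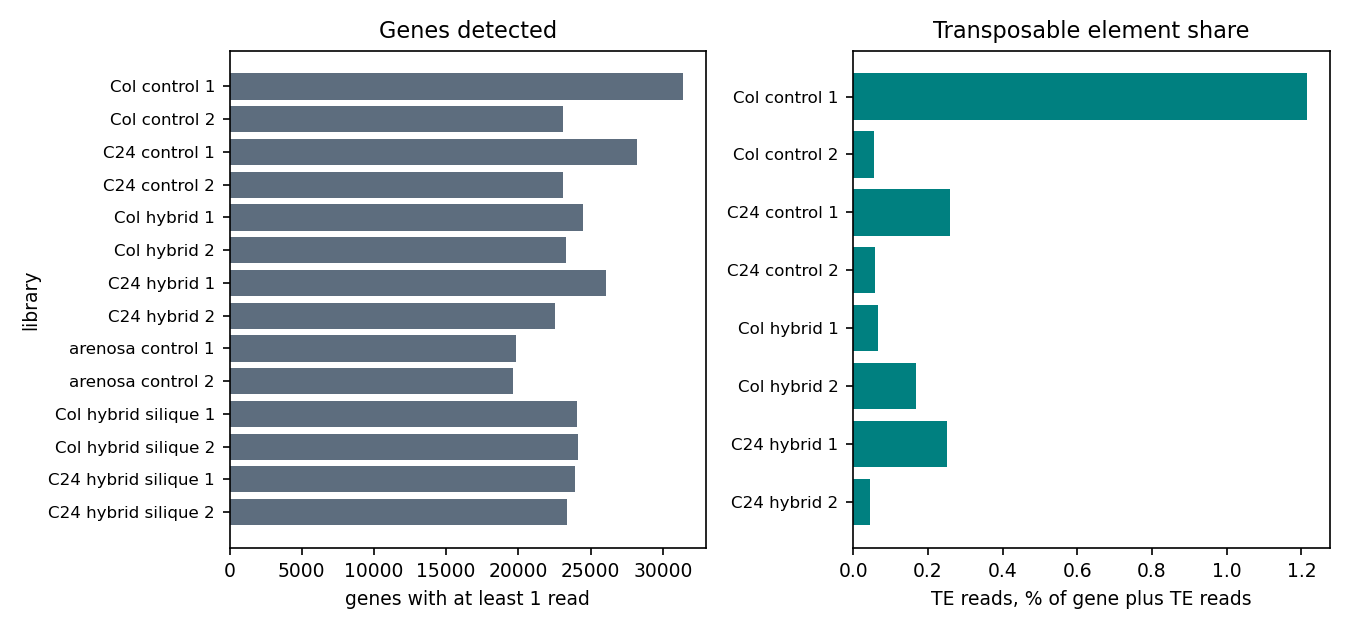
Bars give, per library, the number of genes with at least 1 read (left) and the percent of gene plus TE reads that fell on TEs (right, the 8 libraries of the TE table). Col control 1 stands at 31430 genes and 1.215%, above the other libraries, which reach at most 28243 genes and 0.258%.

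Col hybrid seeds were compared with Col control seeds for the changes in the incompatible cross. Of 20552 genes tested, 3454 (16.8%) changed, 2143 upwards and 1311 downwards. Of 20 photosynthesis genes 12 rose. In the type I MADS-box, imprinted and endosperm (embryo-nourishing tissue) lists, VIM5, HDG9, AGL35 and IKU1 rose, while FIS2, AGL96, FWA and ZOU fell. With upper quartile scaling, which moved the median log2 fold change of all genes from -0.01 to -0.16, the split was 1338 up and 1992 down. The split was near even at a minimum of 5 CPM (1727 up and 1689 down). The count of changed genes was 1748 without Col control 1 (862 up and 886 down), 1275 without Col hybrid 1 (943 and 332) and 1743 without Col hybrid 2 (1146 and 597). It was 1357 (686 and 671) without replicate 1 of both A. thaliana controls, 2236 in a fit of the compared groups only and 1056 in a fit over all 7 groups.

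Of 17 type I MADS-box genes in this comparison, transcription factors many of which act in the endosperm or female gametophyte, 4 rose and 3 fell (6 and 5 adjusted over the list alone). Without Col control 1, or without replicate 1 of both A. thaliana controls, 1 rose and 2 fell, and in the fit over all 7 groups 2 rose and 1 fell. The list did not stand apart from other genes (camera adjusted p = 0.963), and its median of 0.37 differed in sign from its mean of -0.45 and from the downward test. That median was negative with no filter (-0.56), with DESeq2 (-0.66) and over genes with unique sequence only (-1.01). AGL35 (AT5G26630) rose from 12.1 ± 0.878 to 42.8 ± 12 CPM (1.81 ± 0.23, adjusted p = 0.00246), and AGL96 (AT5G06500) fell from 11.5 ± 1.81 to 0.715 ± 0.492 CPM (-4.19 ± 0.41, adjusted p = 0.000868). AGL62 (AT5G60440), which holds back cellularisation of the endosperm, rose from 15.4 ± 3.68 to 37.6 ± 12.1 CPM (1.27 ± 0.36, adjusted p = 0.0444). Its call ended without Col control 1 (adjusted p = 0.173), without replicate 1 of both A. thaliana controls (0.188), without Col hybrid 2 (0.137), with RLE (0.0508) or upper quartile scaling (0.0659) and in the fit over all 7 groups (0.0893).

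Of 20 imprinted and FIS-PRC2 genes, whose products include the Polycomb complex of the endosperm, 6 rose and 3 fell in Col hybrid seeds (8 and 3 adjusted over the list alone; camera adjusted p = 0.382, median 0.49), and 2 rose and 2 fell in the fit over all 7 groups. VIM5 (AT1G57800), of a family that maintains DNA methylation, rose from 10.0 ± 3.4 to 82.4 ± 4.26 CPM (3.03 ± 0.29, adjusted p = 0.000774). The homeodomain gene HDG9 (AT5G17320) rose from 19.8 ± 0.724 to 82.6 ± 5.62 CPM (2.06 ± 0.24, adjusted p = 0.00203). FIS2 (AT2G35670), a Polycomb subunit of the endosperm, fell from 12.1 ± 4.61 to 0.608 ± 0.526 CPM (-4.09 ± 0.49, adjusted p = 0.00203). FWA (AT4G25530), an imprinted gene expressed from the maternal copy, fell from 56.9 ± 1.57 to 15.6 ± 2.48 CPM (-1.86 ± 0.24, adjusted p = 0.00293). Among 7 regulators of endosperm growth, 2 rose (IKU1 and AGL62) and 1 fell (ZOU), with the same counts adjusted over the list alone, and 1 rose and 1 fell without Col control 1, Col hybrid 2 or replicate 1 of both A. thaliana controls and in the fit over all 7 groups (camera adjusted p = 0.966). IKU1 (AT2G35230) went from 20.9 ± 0.523 to 50.4 ± 4.02 CPM (1.27 ± 0.15, adjusted p = 0.00181), and ZOU (AT1G49770), a factor needed for endosperm breakdown, from 6.77 ± 0.639 to 0.446 ± 0.371 CPM (-4.12 ± 0.64, adjusted p = 0.00539).

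Of 20 photosynthesis genes, 12 rose in Col hybrid seeds, also adjusted over the list alone, and 8 were not called. The list lay above other genes (camera adjusted p = 1.42e-08, median 0.87; adjusted p = 0.846 with an estimated correlation). Without Col control 1, 7 rose, without replicate 1 of both A. thaliana controls, 6, and in the fit over all 7 groups, 2. LHCA1 (AT3G54890), of the antenna of photosystem I, rose from 61.8 ± 6.53 to 198 ± 25.1 CPM (1.68 ± 0.18, adjusted p = 0.0012), and LHCB1.2 (AT1G29910, 25.1% not unique) from 20.3 ± 1.83 to 52.6 ± 16.2 CPM (1.38 ± 0.22, adjusted p = 0.00605). Of 21 cell cycle genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.421), with 2 without Col control 1, 1 without Col hybrid 1 and 3 without Col hybrid 2. edgeR called 0 of them without replicate 1 of both A. thaliana controls or in the fit over all 7 groups (9 at an unadjusted p under 0.05 with all libraries, and 4 called by DESeq2). The mitotic kinase gene CDKB2;1 (AT1G76540) went from 5.51 ± 0.878 to 14.8 ± 2.72 CPM (1.43 ± 0.24, adjusted p = 0.00698), a call that ended in the fit over all 7 groups (0.086) and without replicate 1 of both A. thaliana controls (0.0532). Of 20 DNA methylation and RNA silencing genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.129), with 8 at an unadjusted p under 0.05 and 3 called by DESeq2. edgeR called 3 without Col control 2, and 0 without Col control 1, Col hybrid 1, Col hybrid 2 or replicate 1 of both A. thaliana controls and in the fit over all 7 groups.

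Of 24 seed coat and flavonoid genes, 3 fell in Col hybrid seeds, also adjusted over the list alone (camera adjusted p = 0.421), and 1 fell without Col control 2, Col hybrid 1 or Col hybrid 2. BAN (AT1G61720), the anthocyanidin reductase of the seed coat, went from 2010 ± 52.2 to 825 ± 240 CPM (-1.28 ± 0.22, adjusted p = 0.00787). The MADS-box gene STK (AT4G09960) fell from 705 ± 44.0 to 374 ± 58.0 CPM (-0.91 ± 0.17, adjusted p = 0.00956), a call that ended without Col control 2 (0.0631), Col hybrid 1 (0.138) or Col hybrid 2 (0.0625). In the list of 11 WRKY genes, factors of the defence response, WRKY33 (AT2G38470) fell from 7.03 ± 3.87 to 2.05 ± 0.0525 CPM (-1.77 ± 0.45, adjusted p = 0.0303), which also held adjusted over the list alone. This call ended without Col control 2 (0.201), Col hybrid 1 (0.14) or Col hybrid 2 (0.0913) and in the fit over all 7 groups (0.0577), and 2 WRKY genes were called lower without Col control 1. Of 10 seed storage and oil body genes, SESA4 (AT4G27170) alone passed the filter. It had 0 reads in Col hybrid seeds and 1.34 ± 1.64 CPM in the control, and it was not called by edgeR (adjusted p = 0.0534), though its unadjusted p was under 0.05 and it was called lower when adjusted over the list alone. Of the list, 1 gene was called lower by DESeq2, which tested all 10, and 1 without Col control 2, where 7 passed the filter.

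By the rule of largest change, the highest loci in Col hybrid seeds were mainly ribosomal RNA loci. The 18S locus AT2G01010 (96.5% not unique) had 2420 ± 142 CPM against 0.659 ± 0.332 CPM in the control, and the plastid 23S loci ATCG00950 and ATCG01180, with no read in the control, were at least 2340-fold higher. The treatment of reads with several matches was not given in the sources used here and may have differed between groups. These values are therefore uncertain as effects of hybridisation. AT2G01010 had 6 and 11 reads in Col hybrid silique 1 and 2. Another locus, AT3G41768, chosen after its values were seen, had 20259 and 16924 reads in Col control 1 and 2 and 85696 and 44426 in Col hybrid 1 and 2, and it was not called (2.23 ± 0.75, adjusted p = 0.0762). EXPA22 (AT5G39270), an expansin that loosens cell walls (48.1% not unique), stood at 78.1 ± 24.4 CPM, with 1 to 3 reads in the control and a ratio of 1110 (95% interval 306 to 9140). The next genes, chosen after their values were seen, included AT1G36240, with a ratio of 447 (123 to 3700), and sks8 (AT1G21850), which rose from 4.17 ± 1.94 to 469 ± 2.01 CPM (6.81 on the log2 scale). Among the lowest, TPPI (AT5G10100), a trehalose phosphate phosphatase gene, fell from 643 ± 354 to 4.52 ± 0.541 CPM (-7.13 ± 0.8, adjusted p = 0.00164). LCR35 (AT2G22121), of a family of small cysteine-rich peptides, fell from 47.5 ± 0.65 to 0.182 ± 0.0897 CPM (-7.82 ± 0.29, adjusted p = 8.78e-06). AT4G32380 went from 99.0 ± 8.03 to 0.834 ± 0.659 CPM, AT1G56233 from 97.5 ± 17.5 to 0.893 ± 0.743 CPM, and AT5G07260, at 13.8 ± 1.75 CPM in the control and without a read in the hybrid, was at least 51.3-fold lower.

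C24 hybrid seeds were compared with C24 control seeds for the changes in the compatible cross. Here 6536 of 20552 genes (31.8%) changed, 3443 upwards and 3093 downwards. Genes that rose included members of the type I MADS-box, photosynthesis, DNA methylation and cell cycle lists, and genes that fell included members of the seed coat list. The count of changed genes was 3543 without C24 control 1, 2736 without C24 control 2, 3098 without C24 hybrid 1 and 3305 without C24 hybrid 2. It was 4118 without replicate 1 of both A. thaliana controls and 3931 in a fit over all 7 groups.

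Of 17 type I MADS-box genes, 7 rose in C24 hybrid seeds, also adjusted over the list alone, and 10 were not called (camera adjusted p = 0.00127, median 0.85; adjusted p = 0.731 with an estimated correlation). AGL35 rose from 5.69 ± 0.436 to 48.0 ± 10.4 CPM (3.08 ± 0.24, adjusted p = 0.000191), and AGL36 (AT5G26650, 32.9% not unique) from 3.19 ± 0.429 to 66.6 ± 45.1 CPM (4.38 ± 0.53, adjusted p = 0.000798). AGL62 rose from 8.84 ± 1.32 to 66.0 ± 32.2 CPM (2.9 ± 0.38, adjusted p = 0.00111), and AGL96 from 10.3 ± 0.0788 to 39.8 ± 11.9 CPM (1.95 ± 0.27, adjusted p = 0.0015). Of 20 imprinted and FIS-PRC2 genes 8 rose and 1 fell (8 and 2 adjusted over the list alone), and 7 rose and 2 fell without C24 control 2. That list lay above other genes (camera adjusted p = 0.0102, median 0.72; adjusted p = 0.731 with an estimated correlation). VIM5 rose from 9.67 ± 0.495 to 98.3 ± 33.2 CPM (3.35 ± 0.29, adjusted p = 0.000266), and the auxin synthesis gene YUC10 (AT1G48910) from 0.822 ± 0.0491 to 13.1 ± 7.77 CPM (3.98 ± 0.51, adjusted p = 0.00107). FIS2 fell from 23.8 ± 7.0 to 2.05 ± 0.212 CPM (-3.53 ± 0.42, adjusted p = 0.000763).

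Of 7 endosperm growth regulators, 3 rose and 2 fell in C24 hybrid seeds, with the same counts adjusted over the list alone (camera adjusted p = 0.0698). Without C24 control 1, C24 hybrid 1, C24 hybrid 2 or replicate 1 of both A. thaliana controls, or in the fit over all 7 groups, 1 fell. MINI3 (AT1G55600), a WRKY factor of endosperm growth, rose from 4.6 ± 0.637 to 24.6 ± 6.19 CPM (2.42 ± 0.22, adjusted p = 0.000307), and ZOU fell from 12.3 ± 3.43 to 2.01 ± 1.43 CPM (-2.6 ± 0.5, adjusted p = 0.00558). Of 13 embryo regulators, 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.918). These counts were 2 and 1 without C24 control 1, C24 control 2, C24 hybrid 2 or replicate 1 of both A. thaliana controls and in the fit over all 7 groups, and 1 and 1 without C24 hybrid 1. LEC1 (AT1G21970), a master regulator of embryo development, fell from 22.2 ± 14.5 to 1.99 ± 0.641 CPM (-3.46 ± 0.48, adjusted p = 0.0014), and PDF1 (AT2G42840), a marker of the outer cell layer, rose from 13.4 ± 3.34 to 80.6 ± 23.5 CPM (2.59 ± 0.44, adjusted p = 0.00343).

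Of 20 photosynthesis genes, 19 rose in C24 hybrid seeds, also adjusted over the list alone, and 12 rose without C24 control 2 and 11 in the fit over all 7 groups (camera adjusted p = 2.9e-16, median 1.34; adjusted p = 0.604 with an estimated correlation). LHCB2.1 (AT2G05100, 34.4% not unique) rose from 12.4 ± 2.27 to 97.6 ± 17.0 CPM (2.98 ± 0.19, adjusted p = 7.99e-05), and LHCA1 from 39.9 ± 5.84 to 172 ± 23.1 CPM (2.11 ± 0.18, adjusted p = 0.00026). Of 20 DNA methylation and RNA silencing genes 10 rose (11 adjusted over the list alone; camera adjusted p = 0.00127, and 0.731 with an estimated correlation). This count was 3 without C24 control 1, C24 hybrid 1 or replicate 1 of both A. thaliana controls and in the fit over all 7 groups, and 4 without C24 control 2 or C24 hybrid 2. MET1 (AT5G49160), which maintains CG methylation, rose from 35.0 ± 0.342 to 97.7 ± 12.1 CPM (1.48 ± 0.14, adjusted p = 0.00039), and CMT3 (AT1G69770), which methylates CHG sites, from 39.1 ± 3.56 to 84.5 ± 10.2 CPM (1.11 ± 0.15, adjusted p = 0.00111). Of 21 cell cycle genes 10 rose (10 up and 1 down adjusted over the list alone; camera adjusted p = 0.0281, and 0.731 with an estimated correlation). Without C24 control 1, 5 rose, without C24 control 2, 5 rose and 1 fell, and without C24 hybrid 1, 4 rose, while 3 rose in the fit over all 7 groups. The replication clamp gene PCNA1 (AT1G07370) rose from 43.9 ± 4.51 to 96.8 ± 3.71 CPM (1.14 ± 0.14, adjusted p = 0.000891).

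Of 24 seed coat and flavonoid genes, 7 fell and 1 rose in C24 hybrid seeds, also adjusted over the list alone (camera adjusted p = 0.0323, median -0.33; adjusted p = 0.731 with an estimated correlation, and 0.0685 over genes with unique sequence only). Without C24 control 1 or C24 hybrid 2, 5 fell, without C24 control 2 or C24 hybrid 1, 4 fell, and the gene that rose was not called without any 1 of these 4 libraries. It was also not called without replicate 1 of both A. thaliana controls, where 5 fell, or in the fit over all 7 groups, where 4 fell. BAN fell from 3450 ± 449 to 919 ± 162 CPM (-1.91 ± 0.22, adjusted p = 0.000748), STK from 480 ± 74.7 to 203 ± 3.07 CPM (-1.24 ± 0.17, adjusted p = 0.00124), and the transferase gene TT19 (AT5G17220) from 1140 ± 94.5 to 401 ± 141 CPM (-1.51 ± 0.29, adjusted p = 0.00565). Of 21 jasmonate and ethylene genes 6 rose (5 adjusted over the list alone; camera adjusted p = 0.411), with 5 up and 1 down without C24 control 1, 2 and 1 without C24 control 2, 3 up without C24 hybrid 2 and 1 up in the fit over all 7 groups. ERF105 (AT5G51190), an ethylene response factor gene, rose from 1.15 ± 0.701 to 7.15 ± 1.92 CPM (2.62 ± 0.43, adjusted p = 0.00284). Among the largest changes, ribosomal RNA loci again stood highest, with AT2G01010 (96.5% not unique) at 2270 ± 215 against 0.788 ± 0.556 CPM. AT1G36240 had no read in the control and 45.9 ± 10.2 CPM in the hybrid, at least 233-fold higher. At the other end, TPPI fell from 437 ± 386 to 4.33 ± 0.104 CPM, AT5G59845 from 437 ± 13.3 to 20.0 ± 0.511 CPM, and the glutathione transferase gene GSTF14 (AT1G49860) from 40.9 ± 12.9 to 2.6 ± 1.83 CPM (-3.99 ± 0.4).

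The hybrid effects of both crosses overlapped. Of the genes called in each, 1550 were higher in both hybrids, against 359 for independent lists, and 916 were lower in both, against 197.3, while 67 went in opposite directions. Across the 20552 genes, which are not independent replicates, the fold changes of both crosses had a Pearson r of 0.579 and a Spearman rho of 0.612. VIM5, HDG9, AGL35, IKU1, LHCA1 and sks8 were among the genes called higher in both, and FIS2, ZOU, BAN, STK and TPPI among those called lower in both. AGL96 was called in opposite directions.

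**Figure D2:**
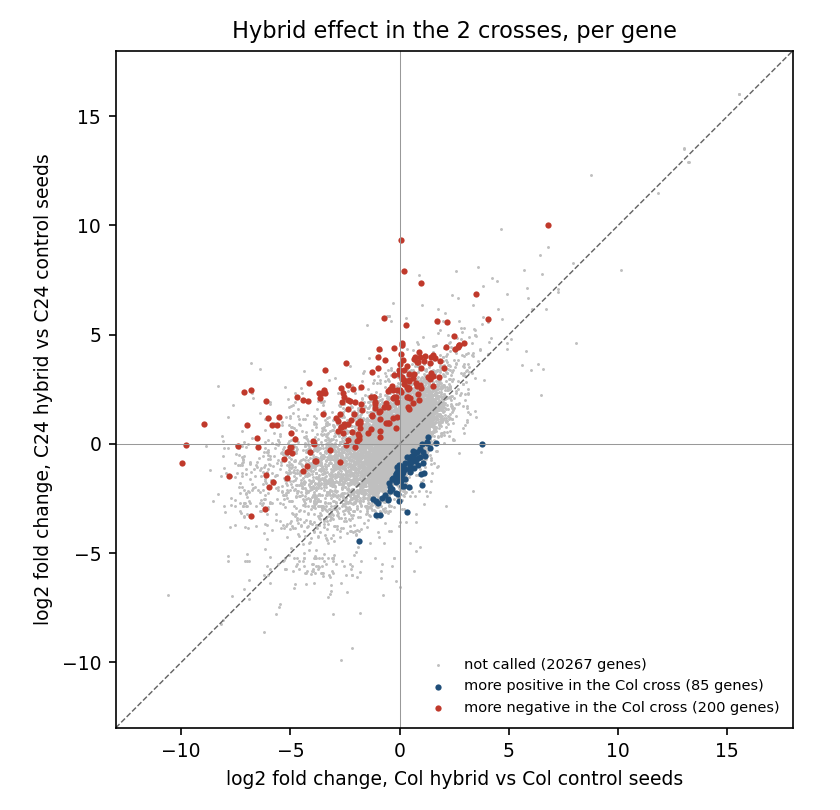
Each point is a gene, with its log2 fold change in Col hybrid against Col control seeds (x axis) and in C24 hybrid against C24 control seeds (y axis). The 285 genes whose effects differed between the crosses are coloured, 85 more positive and 200 more negative in the Col cross (226 and 231 without Col hybrid 1, 286 and 328 with DESeq2, 11 and 142 without replicate 1 of both A. thaliana controls), and the dashed line marks equal effects.

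The Col and C24 hybrids were next compared directly, and the difference between their hybrid effects was tested as an interaction. Between Col and C24 hybrid seeds 2009 genes differed, 1068 higher and 941 lower in Col. The hybrid effect itself differed for 285 genes, 85 more positive and 200 more negative in Col, a split that varied with the libraries and the tool. AGL96, FWA and MINI3 were lower in the Col hybrid and differed in their hybrid effect, while the jasmonate genes VSP1, VSP2 and LOX2 were higher in the Col hybrid. Between hybrids the count was 1304 without Col hybrid 1, 1325 without Col hybrid 2, 1042 without C24 hybrid 1 and 1140 in a fit over all 7 groups. For the interaction it was 445 without C24 control 1 (122 more positive and 323 more negative), 457 without Col hybrid 1 (226 and 231) and 542 without C24 hybrid 2 (141 and 401). It was 153 without replicate 1 of both A. thaliana controls (11 and 142), 1052 with no filter (425 and 627), 614 with DESeq2 (286 and 328) and 33 in a fit over all 7 groups (8 and 25). The more positive genes numbered 36 of 240 without Col control 1, 128 of 422 without Col control 2, 44 of 269 without Col hybrid 2 and 30 of 190 without C24 hybrid 1. With upper quartile scaling the median interaction of all genes was -0.13, against -0.02.

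Among type I MADS-box genes, 3 of 17 tested were lower in the Col hybrid than in the C24 hybrid (7 adjusted over the list alone; camera adjusted p = 0.00172, median -1.28; adjusted p = 0.978 with an estimated correlation). Without Col hybrid 1, 1 was lower, without C24 hybrid 1, 1 was lower and 2 were higher, and without C24 hybrid 2, 8 were lower. There were 7 lower without replicate 1 of both A. thaliana controls and 1 in the fit over all 7 groups. In the interaction, 1 of the 17 was called, more negative in Col (8 adjusted over the list alone), and the list lay below other genes (camera adjusted p = 6.37e-08, median -1.66; adjusted p = 0.43 with an estimated correlation). That count was 3 without C24 control 1, 2 without Col hybrid 2 and 7 without C24 hybrid 2. The called gene, AGL96, had 0.715 ± 0.492 CPM in the Col hybrid and 39.8 ± 11.9 CPM in the C24 hybrid (-5.98 ± 0.4, adjusted p = 7.42e-05), and its hybrid effect was lower in Col by an interaction of -6.14 ± 0.49 (adjusted p = 0.00142). The interactions of AGL62 (-1.63 ± 0.51, adjusted p = 0.177), AGL35 (-1.27 ± 0.33, adjusted p = 0.111) and AGL36 (-2.36 ± 0.67, adjusted p = 0.141; 32.9% not unique) did not pass.

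Of 20 imprinted and FIS-PRC2 genes, FWA was called in both tests, also adjusted over the list alone, with camera adjusted p = 0.133 between hybrids and 0.0365 in the interaction (median -0.34; adjusted p = 0.636 with an estimated correlation). Between hybrids, 2 were lower in Col without Col hybrid 1, 1 was lower and 1 higher without C24 hybrid 1, and 4 were lower without C24 hybrid 2, which also gave 4 in the interaction. FWA stood at 15.6 ± 2.48 CPM in the Col hybrid and 62.0 ± 22.4 CPM in the C24 hybrid (-1.98 ± 0.25, adjusted p = 0.00164; interaction -2.2 ± 0.33, adjusted p = 0.0201). Among 7 endosperm growth regulators MINI3 was called in both tests, and 2 genes were called in each when adjusted over the list alone (camera adjusted p = 0.133 between hybrids; 0.00274 in the interaction, median -1.52, and 0.309 with an estimated correlation). Between hybrids, 2 were called without Col hybrid 2, 3 without C24 hybrid 2 and 0 in edgeR without C24 hybrid 1, where MINI3 had an adjusted p of 0.0551; with all libraries 3 had an unadjusted p under 0.05 and DESeq2 called 2. In the interaction 2 were called without C24 hybrid 2. MINI3 had 9.9 ± 0.807 CPM in the Col hybrid and 24.6 ± 6.19 CPM in the C24 hybrid (-1.3 ± 0.21, adjusted p = 0.00585), with an interaction of -2.93 ± 0.3 (adjusted p = 0.00438). In the fit over all 7 groups the interactions of FWA and MINI3 (adjusted p = 0.0886 and 0.0606) and the difference of MINI3 between hybrids (0.0622) did not pass.

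Of 21 jasmonate and ethylene genes, 5 were higher in the Col hybrid than in the C24 hybrid (6 adjusted over the list alone; camera adjusted p = 0.0797, median 0.58), with 3 without Col hybrid 1 and in the fit over all 7 groups, 4 higher and 1 lower without Col hybrid 2, and 5 and 1 without replicate 1 of both A. thaliana controls. The storage protein genes VSP2 (AT5G24770) and VSP1 (AT5G24780) had 11.5 ± 2.72 and 13.0 ± 5.05 CPM in the Col hybrid against 1.15 ± 0.0965 and 1.95 ± 0.447 CPM in the C24 hybrid (3.31 ± 0.42, adjusted p = 0.0018, and 2.76 ± 0.35, adjusted p = 0.00183). The lipoxygenase gene LOX2 (AT3G45140) had 7.99 ± 1.78 against 2.27 ± 1.02 CPM (1.83 ± 0.35, adjusted p = 0.0129). Among 15 salicylate and immune genes, ALD1 (AT2G13810), which acts in pipecolate synthesis, was higher at 24.8 ± 6.29 against 0.29 ± 0.282 CPM (6.32 ± 0.6, adjusted p = 0.000415). SAG101 (AT5G14930), an immune regulator, was lower in the Col hybrid, at 13.3 ± 0.892 against 25.1 ± 6.28 CPM (-0.92 ± 0.18, adjusted p = 0.0156), a call that ended without Col hybrid 1 (0.126), Col hybrid 2 (0.107) or C24 hybrid 2 (0.361). ALD1 and SAG101 were also the calls adjusted over the list alone (list camera adjusted p = 0.978).

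In the interaction, edgeR called 0 of the 15 salicylate and immune genes (2 at an unadjusted p under 0.05, 0 by DESeq2) and 0 of the 20 DNA methylation and RNA silencing genes (4 and 0), none also adjusted over the list alone. Both lists lay below other genes in camera (adjusted p = 0.0365, median -0.78, and 0.0405, median -0.23), which was lost with an estimated correlation (adjusted p = 0.309 and 0.614). Without Col control 1, 2 salicylate genes were called, and without C24 hybrid 2, 1 of each list. In the WRKY list of 11, WRKY33 was called, also adjusted over the list alone, with an interaction of -3.62 ± 0.67 (adjusted p = 0.0435; list camera adjusted p = 0.0133, median -1.21, and 0.309 with an estimated correlation). That call ended without Col control 2 (0.0728) or Col hybrid 1 (0.0535) and in the fit over all 7 groups (0.0922), and 2 WRKY genes were called without C24 control 1 or without replicate 1 of both A. thaliana controls. Of 20 photosynthesis genes LHCB2.1 was called (2 adjusted over the list alone; camera adjusted p = 1.27e-06, median -0.52, and 0.43 with an estimated correlation). Its interaction of -1.6 ± 0.26 (adjusted p = 0.0242) ended without C24 control 2 (0.112), Col hybrid 2 (0.0587), C24 hybrid 1 (0.0862) or replicate 1 of both A. thaliana controls (0.0588) and in the fit over all 7 groups (0.67), and 2 of the list were called without Col control 1.

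Among the largest interactions, AT4G32380 fell in the Col cross from 99.0 ± 8.03 to 0.834 ± 0.659 CPM, while C24 hybrid and control seeds had 432 and 83.0 CPM (-9.50 ± 0.64). AT1G56233 went from 97.5 to 0.893 CPM in the Col cross and from 39.8 to 73.4 CPM in the C24 cross (-7.89). ARF13 (AT1G34170), of the auxin response factor family, had no read in the Col hybrid, 8.92 ± 2.58 CPM in the Col control, and 5.39 ± 2.63 and 9.96 ± 2.15 CPM in C24 hybrid and control. On the positive side, AIR1 (AT4G12550, 20.1% not unique) had 25.7 ± 11.9 CPM in the Col hybrid against 1.83 ± 0.189 CPM in its control, and 12.8 ± 1.66 against 13.0 ± 2.74 CPM in the C24 cross (3.81). JR1 (AT3G16470), a jasmonate-responsive gene, had 67.6 against 53.2 CPM in the Col cross and 22.9 against 201 CPM in the C24 cross (3.49), and the metallothionein gene MT2A (AT3G09390) 158 against 118 and 26.4 against 102 CPM (2.37). The call of MT2A ended without replicate 1 of both A. thaliana controls (adjusted p = 0.0691), and those of AT4G32380 (0.0754) and ARF13 (0.0651) in the fit over all 7 groups.

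**Figure D3:**
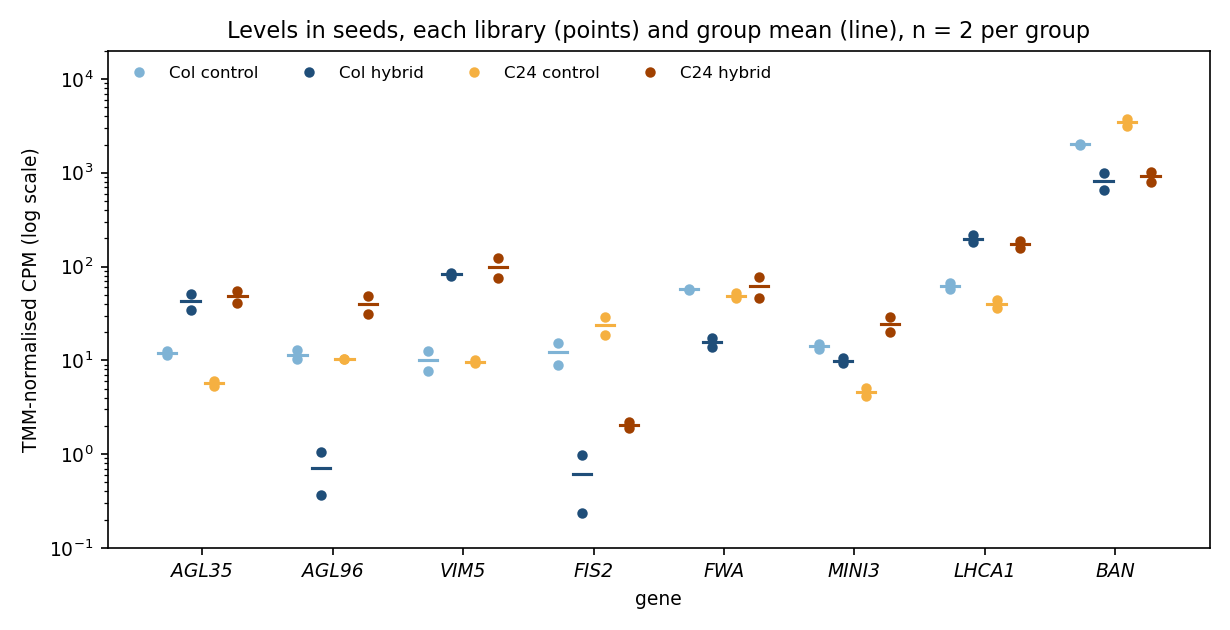
Points give the level of each library in TMM-normalised CPM (log axis) for 8 genes in Col control, Col hybrid, C24 control and C24 hybrid seeds, and lines give the group means of 2 libraries. AGL96 lies at 0.715 CPM in the Col hybrid and 39.8 CPM in the C24 hybrid, while VIM5 and LHCA1 lie above the controls in both hybrids and BAN below.

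The Col and C24 controls were compared to see which differences between accessions exist without hybridisation. In control seeds 3444 of 20552 genes differed, 1613 higher and 1831 lower in Col. How well reads of each accession match the A. thaliana genome used for counting was not examined, and some of these differences may reflect it. Genes higher in Col included members of the jasmonate list, and genes lower in Col members of the seed coat list. ALD1 stood at 47.7 ± 13.2 CPM in Col and 0.724 ± 0.653 CPM in C24 (6.02 ± 0.49, adjusted p = 0.000166), so the ALD1 difference was present in controls and hybrids alike. Of the genes called in both, 669 were higher in Col in control and hybrid seeds, against 83.8 for independent lists, 466 were lower in both, against 83.8, and 65 went in opposite directions. With upper quartile scaling the split was 1948 higher and 1319 lower and the median 0.11, against 0.01. The count was 1950 without Col control 1 (1181 higher and 769 lower in Col), 2082 without C24 control 1 (1109 and 973), 1578 without C24 control 2 (937 and 641), 1142 without replicate 1 of both (704 and 438), and 1802 in a fit over all 7 groups (1083 and 719).

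Of 21 jasmonate and ethylene genes, 8 were higher and 1 lower in Col control seeds (10 and 1 adjusted over the list alone; camera adjusted p = 0.000727, median 1.31; adjusted p = 0.845 with an estimated correlation), with 5 higher without Col control 2 and in the fit over all 7 groups and 12 without replicate 1 of both A. thaliana controls, and the lower gene was not called in any of these or without Col control 1. VSP1 had 11.9 ± 0.45 against 2.37 ± 0.751 CPM (2.33 ± 0.33, adjusted p = 0.00279) and LOX2 9.25 ± 2.09 against 2.2 ± 0.0534 CPM (2.07 ± 0.34, adjusted p = 0.00513), and the call of LOX2 ended without replicate 1 of both A. thaliana controls (0.0679). Of 11 WRKY genes 4 were higher (5 adjusted over the list alone; camera adjusted p = 0.0866) 1 without Col control 2 and 2 in the fit over all 7 groups. WRKY33 had 7.03 ± 3.87 against 0.592 ± 0.0949 CPM (3.55 ± 0.49, adjusted p = 0.00255). Photosynthesis genes were higher for 7 of 20 and lower for 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.000727, and 0.845 with an estimated correlation). These counts were 5 higher without Col control 1, 2 and 1 without Col control 2, 3 and 1 without C24 control 1, 1 higher without C24 control 2, and 3 higher without replicate 1 of both A. thaliana controls. In the fit over all 7 groups edgeR called 0 (15 at an unadjusted p under 0.05 with all libraries, and 12 called by DESeq2). MINI3 was higher in Col, at 14.2 ± 1.25 against 4.6 ± 0.637 CPM (1.63 ± 0.22, adjusted p = 0.00216), and so was AGL36 (32.9% not unique), at 21.6 ± 4.1 against 3.19 ± 0.429 CPM (2.76 ± 0.52, adjusted p = 0.00942). Of 24 seed coat genes 4 were lower in Col (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.131), 1 without Col control 2 or C24 control 2, and 0 in edgeR without Col control 1, without replicate 1 of both A. thaliana controls or in the fit over all 7 groups; with all libraries 8 had an unadjusted p under 0.05 and DESeq2 called 6.

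A. arenosa control seeds were compared with both A. thaliana controls for the differences between the parent species, with all reads counted on the A. thaliana genome. Against Col 10588 of 21619 genes differed, 4346 higher and 6242 lower in A. arenosa, and against C24 11574, 4848 higher and 6726 lower. Most pollen, photosynthesis and cell cycle genes of the lists were higher in A. arenosa, and most type I MADS-box, imprinted and seed coat genes lower. The median log2 fold change of all genes was -0.25 against Col, -0.16 with upper quartile and -0.13 with RLE scaling, and -0.24 against C24, -0.04 and -0.08 with these scalings. In a fit of the compared groups only, the count against Col was 6901.

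Of 17 type I MADS-box genes 15 were lower in A. arenosa than in Col, also adjusted over the list alone (camera adjusted p = 0.000257; adjusted p = 0.484 with an estimated correlation). In 11 of them a group had no read, and the median of -7.7 was -3.1 with these at their bound. AGL96 was at least 8.88-fold lower and AGL62 lower by a ratio of 64.2 (95% interval 11.5 to 2540). Of 20 imprinted genes 12 were lower and 1 higher (13 and 1 adjusted over the list alone; camera adjusted p = 0.000561, and 0.449 with an estimated correlation; median -4.26, at bounds -1.59), and FWA, without a read in A. arenosa, was at least 44.3-fold lower. Of 24 seed coat and flavonoid genes 19 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 3.82e-17, median -3.26; adjusted p = 0.246 with an estimated correlation). The higher gene was not called without Col control 1, A. arenosa control 1 or replicate 1 of both A. thaliana controls. CHS (AT5G13930), chalcone synthase, had 317 ± 19.2 CPM against 9720 ± 839 CPM in Col (-4.94 ± 0.23, adjusted p = 2.06e-06), and DFR (AT5G42800) 28.7 ± 12.5 against 3080 ± 248 CPM (-6.75 ± 0.36, adjusted p = 2.94e-06).

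All 20 photosynthesis genes were higher in A. arenosa than in Col, also adjusted over the list alone (camera adjusted p = 1.01e-15, median 3.43; adjusted p = 0.441 with an estimated correlation). LHCA1 had 1270 ± 482 against 64.9 ± 11.7 CPM (4.29 ± 0.32, adjusted p = 1.24e-05). Of 12 pollen genes tested 9 were higher, also adjusted over the list alone (camera adjusted p = 0.000284, median 7.37; adjusted p = 0.484 with an estimated correlation). The pollen pectinesterase gene VGD1 (AT2G47040, 11.5% not unique) had 3170 ± 3390 against 6.45 ± 6.47 CPM (8.93 ± 1.18). Of 22 cell cycle genes 16 were higher and 2 lower (16 and 3 adjusted over the list alone; camera adjusted p = 5.84e-05, median 1.74; adjusted p = 0.441 with an estimated correlation), with 13 and 1 without Col control 2 and 15 and 1 without A. arenosa control 1. The cytokinesis kinesin gene HIK (AT1G18370) had 23.9 ± 1.4 against 2.45 ± 0.218 CPM (3.28 ± 0.29, adjusted p = 2.86e-05). Against C24, 13 type I MADS-box genes were lower, 19 seed coat genes lower and 1 higher, 20 photosynthesis genes higher and 11 of 12 pollen genes higher (13, 20 and 1, 20 and 11 adjusted over the list alone), with camera adjusted p of 0.00247, 4.62e-17, 2.44e-16 and 0.000355, and adjusted p of 0.503, 0.255, 0.34 and 0.469 with an estimated correlation. The higher seed coat gene was not called there without C24 control 1, C24 control 2, A. arenosa control 1 or replicate 1 of both A. thaliana controls.

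Among genes beyond both parents, 548 differed in the Col hybrid from its maternal-line control and from A. arenosa in the same direction, 437 higher and 111 lower, and 1498 did so in the C24 hybrid, 972 higher and 526 lower. Both comparisons share the hybrid libraries. The A. arenosa control had 1777781 and 2089616 gene reads, counted on the A. thaliana genome, and may hold RNA of other tissues. A gene that is low there for such reasons can pass as higher than both parents once it exceeds the maternal-line control. In 10 simulations of unchanged groups tested with edgeR the count was 0.1 on average for Col (highest 1) and 0 for C24. All groups there shared 1 mean per gene, so counts near 0 were bound to result. In the data 10756 genes were called between the Col hybrid and A. arenosa, and 11067 for the C24 hybrid. The simulations therefore cannot show how many genes would pass through a difference between the species. Independent lists would give 186.1 higher and 90.4 lower for Col, and 520.3 and 400.4 for C24. The highest were ribosomal RNA loci in both. TPPI lay below both parents in the Col hybrid, at 4.69 CPM against 659 ± 319 CPM in the Col control and 1250 ± 398 CPM in A. arenosa (-7.12), and also in the C24 hybrid (-6.72). The Col split was 338 higher and 255 lower with upper quartile and 409 and 178 with RLE scaling, 397 and 243 at a minimum of 5 CPM, 720 and 430 with no filter and 175 and 8 without Col hybrid 1. The Col count was 148 without Col control 1, 171 without Col control 2, 183 without Col hybrid 1, 242 without Col hybrid 2, 1063 without A. arenosa control 1, 1529 without A. arenosa control 2, 57 without replicate 1 of both A. thaliana controls, 1150 with no filter and 1137 with DESeq2. The C24 count was 671 without C24 control 1, 444 without C24 control 2, 527 without C24 hybrid 1, 818 without C24 hybrid 2 (649 higher and 169 lower) and 371 without replicate 1 of both A. thaliana controls.

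Whole siliques of the hybrid crosses, which hold the seeds as well as the tissues of the fruit, were compared with seeds of the same crosses. In the Col hybrid 11014 of 20700 genes differed, 6162 higher and 4852 lower in siliques, and in the C24 hybrid 12164, 6604 higher and 5560 lower. All photosynthesis and egg cell genes tested were higher in siliques, most imprinted and seed coat genes were lower, and fruit markers were split. Pollen markers also differed, with 9 of 11 higher and 1 lower in Col siliques (median 2.5) and 7 of 11 higher in C24 siliques (median 2.22), also adjusted over the list alone (camera adjusted p = 0.0774 and 0.163). In Col 4 were higher without Col hybrid 2 and 5 without Col hybrid silique 1 or in the fit over all 7 groups, and the lower gene was not called without any 1 library. In C24 2 were higher without C24 hybrid 1, and 3 without C24 hybrid 2 or in the fit over all 7 groups. The pollen gene VGD1 (11.5% not unique) had 65.4 ± 39.5 CPM in Col siliques and 12 ± 4.39 CPM in seeds (2.42 ± 0.44, adjusted p = 0.00157). All 20 photosynthesis genes were higher in both crosses, also adjusted over the list alone (Col camera adjusted p = 8.83e-24, median 3.06, and 0.395 with an estimated correlation; C24 1.85e-27, median 3.81, and 0.259). RBCS1B (AT5G38430, 16.6% not unique), a small subunit of Rubisco, had 1550 ± 211 CPM in Col siliques and 17.3 ± 5.31 CPM in seeds (6.47 ± 0.35, adjusted p = 4.75e-06). All 6 egg cell and synergid genes tested were higher in both crosses, also adjusted over the list alone (Col camera adjusted p = 0.00769, median 4.66, at bounds 4.18, and 0.491 with an estimated correlation; C24 0.00486, 6.46, 4.70 and 0.302). With genes of unique sequence only these lists had adjusted p of 0.0789 and 0.0507. EC1.3 (AT2G21750), an egg cell gene without a read in Col hybrid seeds, was at least 19.7-fold higher in siliques.

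Of 5 fruit valve and dehiscence markers, 3 were higher and 2 lower in siliques of each cross, also adjusted over the list alone (camera adjusted p = 0.0774 in Col and 0.0909 in C24). FUL (AT5G60910), a regulator of the fruit valves, had 70.7 ± 1.77 CPM in Col siliques and 0.761 ± 0.397 CPM in seeds (6.4 ± 0.35), while SHP2 (AT2G42830) and SHP1 (AT3G58780), regulators of fruit opening, were lower in Col siliques (-1.02 ± 0.17 and -1.17 ± 0.21). Of 23 jasmonate and ethylene genes 15 were higher and 2 lower in C24 siliques (15 and 3 adjusted over the list alone; camera adjusted p = 0.00103, median 1.31; adjusted p = 0.302 with an estimated correlation), with 12 and 4 without C24 hybrid 1, 15 and 1 without C24 hybrid 2, and 13 and 1 in the fit over all 7 groups. In Col siliques 10 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.0908), with 9 and 2 without Col hybrid 2 and 8 and 2 in the fit over all 7 groups. Their median of 0.13 was -0.07 at a minimum of 5 CPM or over genes with unique sequence only. VSP1 had 3500 ± 354 CPM in Col siliques and 13.6 ± 5.67 CPM in seeds (7.99 ± 0.49, adjusted p = 6.48e-06). Of 14 heat and abiotic stress genes 5 were higher and 3 lower in Col siliques and 6 and 4 in C24 siliques, also adjusted over the list alone (camera adjusted p = 0.14 and 0.45), and without Col hybrid 1, 6 were higher and 1 lower in Col. Of 20 imprinted genes 15 were lower in siliques of each cross (15 in Col and 16 in C24 adjusted over the list alone; camera adjusted p = 2.41e-05 and 5.99e-07, and 0.395 and 0.302 with an estimated correlation). Of 24 seed coat genes 18 were lower in Col siliques, also adjusted over the list alone (camera adjusted p = 1.16e-07, median -1.48; adjusted p = 0.395 with an estimated correlation), and without Col hybrid silique 2, 17 were lower and 1 was higher. In C24 siliques 18 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 5.99e-07, median -1.83; adjusted p = 0.302 with an estimated correlation), and the higher gene was not called without C24 hybrid 1 or C24 hybrid silique 2. AGL62 had 3.59 ± 1.34 CPM in Col siliques and 38.9 ± 11.4 CPM in seeds (-3.42 ± 0.43, adjusted p = 0.000208), and the proton pump gene AHA10 (AT1G17260) 65.1 ± 4.05 and 267 ± 15.9 CPM (-2.04 ± 0.19, adjusted p = 4.52e-05). Of 20 DNA methylation genes 14 were lower in C24 siliques, also adjusted over the list alone (camera adjusted p = 0.000706, median -1.14; adjusted p = 0.348 with an estimated correlation). In Col siliques 12 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.00177, median -0.77; adjusted p = 0.52 with an estimated correlation), and the higher gene was not called without Col hybrid 2.

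Between siliques of the hybrid crosses 892 genes differed, 515 higher and 377 lower in Col. The count was 562 without Col hybrid silique 2, 2019 with no filter, 429 at a minimum of 5 CPM, 567 over genes with unique sequence only and 560 in a fit of the compared groups only. AGL96 was lower in Col siliques, at 0.0908 ± 0.128 CPM from 3 reads, against 5.43 ± 2.11 CPM (adjusted p = 0.00196), and ALD1, without a read in C24 siliques, was at least 7.47-fold higher. Of 11 WRKY genes 3 were lower in Col (5 adjusted over the list alone; camera adjusted p = 0.00863, median -0.73; adjusted p = 0.823 with an estimated correlation), and 1 without Col hybrid silique 1, Col hybrid silique 2 or C24 hybrid silique 2 and in the fit over all 7 groups. WRKY40 (AT1G80840) had 7.21 ± 0.253 against 26.6 ± 5.43 CPM (-1.88 ± 0.26, adjusted p = 0.00262), a call that ended in the fit over all 7 groups (0.107). Of 20 photosynthesis genes 2 were lower in Col (11 adjusted over the list alone; camera adjusted p = 2.54e-08, median -0.71; adjusted p = 0.823 with an estimated correlation), 1 without Col hybrid silique 2 and 4 without C24 hybrid silique 2. LHCB2.2 (AT2G05070, 40.4% not unique) had 489 ± 63.5 against 1820 ± 542 CPM (-1.9 ± 0.27, adjusted p = 0.00321). Of the genes called between hybrid seeds and between hybrid siliques, 283 were higher in Col in both, against 25.7 for independent lists, 153 were lower in both, against 15.5, and 7 went in opposite directions.

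Few TEs were called. Their spread between replicates was large, with a common biological coefficient of variation of 1.65 against 0.229 for genes, and recovery of changed TEs was not simulated, so few calls do not show that few TEs changed. Of 1421 tested, 3 fell in Col hybrid seeds, 3 fell in C24 hybrid seeds, 1 was higher and 1 lower in Col than in C24 hybrids, and 1 differed in the interaction. DESeq2 called 0 in each, and 13, 7, 16 and 9 had an unadjusted p under 0.05 in edgeR. AT2TE26350 fell in both crosses (-3.65 ± 0.58, adjusted p = 0.0127, in Col and -4.23 ± 0.59, adjusted p = 0.00455, in C24). AT1TE67190 was lower in the Col than in the C24 hybrid (-2.33 ± 0.3, adjusted p = 0.00306), and its hybrid effect differed by -3.89 ± 0.41 (adjusted p = 0.000391). AT3TE51710 was higher in the Col hybrid (3.75 ± 0.52, adjusted p = 0.00455), a call that ended without Col hybrid 1 (0.525) or Col hybrid 2 (0.146). The median log2 fold change of all TEs in Col was -2.4, but 2.68 without Col control 1 and -3.66 without Col control 2. In C24 it was -0.06, but 2.45 and -0.63 without C24 control 1 and 2. With factors from the TE counts, 27 TEs were called between hybrids. TE reads were 0.636 ± 0.82% of gene and TE reads in Col controls, 0.158 ± 0.141% in C24 controls, 0.117 ± 0.071% in Col hybrids and 0.147 ± 0.146% in C24 hybrids, differences within the spread of the replicates.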

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

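Of the tests in this part, that of silique tissue in the Col cross alone, those of the reads of Col control 1 and the counts without replicate 1 of both A. thaliana controls were chosen only after the result was seen. The results here are differences between the hybrid effects of the Col and C24 crosses, each tested as an interaction. It passed for 285 genes, 85 more positive and 200 more negative in Col (226 and 231 without Col hybrid 1, 286 and 328 with DESeq2, 11 and 142 without replicate 1 of both A. thaliana controls), and 1 TE, AT1TE67190 (-3.89). Among the fixed lists, camera's adjusted p was 6.37e-08 for type I MADS-box genes, 1.27e-06 for photosynthesis genes, 0.00274 for endosperm growth regulators, 0.0133 for WRKY genes, 0.0365 for imprinted genes, 0.0365 for salicylate and immune genes and 0.0405 for DNA methylation genes. All of these lists were more negative in Col, and none passed with an estimated correlation (adjusted p from 0.309 to 0.636). Among list members the interaction was -6.14 for AGL96, -3.62 for WRKY33, -2.93 for MINI3, -2.20 for FWA and -1.60 for LHCB2.1. The call of WRKY33 ended without Col control 2 (adjusted p = 0.0728 in edgeR) or Col hybrid 1 (0.0535), and that of LHCB2.1 without C24 control 2 (0.112), Col hybrid 2 (0.0587) or C24 hybrid 1 (0.0862). The highest interactions were 3.81 for AIR1, 3.49 for JR1, 2.91 for AT5G09570, 2.59 for AT5G59845, 2.57 for AT2G24110, 2.44 for AOX1A, 2.37 for MT2A and 2.35 for AT5G06330. The lowest were -9.75 for AT2G27936, -9.50 for AT4G32380, -9.26 for AT1G32280, -9.08 for ARF13, -8.07 for AT1G22420, -7.89 for AT1G56233, -7.32 for AT2G19220 and -7.25 for AT5G46810. Of these, AT2G27936, AT1G32280 and ARF13 had a group without reads and AT1G22420 and AT2G19220 a group with 1 read, so their fitted values are no bounds. Without replicate 1 of both A. thaliana controls the calls of AT5G09570 (adjusted p = 0.0776), AT2G24110 (0.157), MT2A (0.0691), AT5G06330 (0.0844) and LHCB2.1 (0.0588) ended. In the fit over all 7 groups those of AT5G09570 (0.0633), AT5G59845 (0.149), AT2G24110 (0.144), AT5G06330 (0.211), AT2G27936 (0.0825), AT4G32380 (0.0754), ARF13 (0.0651), AT2G19220 (0.0886) and AT5G46810 (0.0693) ended. So did those of FWA (0.0886), MINI3 (0.0606), WRKY33 (0.0922) and LHCB2.1 (0.67). Of the 285 genes, 67 were called only in the C24 cross as higher and 50 only there as lower, 11 only in the Col cross as higher and 41 only there as lower. A further 47 went down in Col and up in C24, 16 up in Col and down in C24, 33 up in both and 20 down in both.

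Of 20 photosynthesis genes, 12 were called higher in the Col hybrid (7 without Col control 1, 6 without replicate 1 of both A. thaliana controls, 2 in the fit over all 7 groups) and 19 in the C24 hybrid (12 without C24 control 2, 11 in the fit over all 7 groups), with list medians of 0.87 and 1.34 (camera's adjusted p with an estimated correlation 0.846 and 0.604). Pieces of silique wall left on the hybrid seeds would bring other silique transcripts along, but in the Col cross the 172 silique genes outside the list gained a median of -0.07% of their silique level where the list needed 3.8%. That ratio of -0.018 (95% bootstrap interval over genes -0.065 to 0.024) argues against silique wall as the cause of the Col median. In the C24 cross 262 silique genes gained 1.21% where 4.2% was needed, a ratio of 0.289 (0.224 to 0.389) that lies between the bounds set for the test over both crosses, so there silique tissue and a change within the seed cannot be told apart. The list's median log2 ratio to the A. arenosa control was -3.00 in Col (-3.53 to -2.69) and -3.06 in C24. Levels carried over from that parent may also be a source, open because its libraries held green tissue transcripts. A difference in seed development was not tested.

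Col control 1 had 88221 reads over the 6708 genes without a read in any silique library, against 1158 in Col control 2, 14949 in C24 control 1, 1697 in C24 control 2, 6854 in C24 hybrid 1 and 4720 and 3465 in Col hybrid 1 and 2. Across these genes, which are not independent, reads followed exon length with a Spearman rho of 0.58, as genomic DNA in the library would give, while rho was 0.14 in Col control 2, 0.43 in C24 control 1, 0.38 in C24 hybrid 1 and between 0.05 and 0.28 in the other seed libraries. Greater depth is argued against by the ratio of total counts to Col control 2, 1.006. Genomic DNA is therefore a candidate explanation, although the protocol included a DNase step, and no biological explanation was tested. Without replicate 1 of both A. thaliana controls the interaction passed for 153 genes.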

How the results depend on the processing

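Of the alternatives in this part, genes with unique sequence only and leaving out replicate 1 of both A. thaliana controls were chosen only after the results were seen. No named gene or list test changed direction under the alternatives run, while some genes called but not named did when a library was left out, at most 21 of those called in a comparison. Among the values of named genes, 6477 kept their side of the threshold and 483 lost it. With 2 libraries per group, single libraries moved most counts, and A. arenosa depth limited low transcripts. Where a count moved, the cause was not tested, except that leaving out libraries leaves fewer samples.

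Leaving out 1 library at a time gave 1275 to 3370 genes for Col hybrid against control, 2736 to 3543 for C24 hybrid against control, 1042 to 1517 between hybrids, 190 to 542 for the interaction, 1578 to 3261 between controls, 148 to 1529 beyond both parents in Col, 444 to 2188 beyond both parents in C24 and 562 to 682 between siliques. For TEs it gave 3 to 6 in the Col cross and 1 to 2 between hybrids. Without replicate 1 of both A. thaliana controls the counts were 1357 for Col, 4118 for C24, 153 for the interaction, 1142 between controls, 57 and 371 beyond both parents, and 6, 9 and 21 for TEs in Col, in C24 and between hybrids. Of the 3454 genes called in Col, 1194 were kept there. A fit over all 7 groups gave 1056 for Col, 3931 for C24, 1140 between hybrids, 33 for the interaction and 1802 between controls. The compared groups alone gave 2236 for Col, 6901 for A. arenosa against Col, 560 between siliques and, for TEs, 1, 0 and 7 in Col, in C24 and between hybrids (edgeR; 13, 7 and 16 at an unadjusted p under 0.05 with all groups, and 9 in the interaction). No filter gave 1052 for the interaction, 1150 beyond both parents in Col, 2019 between siliques and, for TEs, 1, 1, 0 and 0 in Col, in C24, between hybrids and in the interaction. A minimum of 5 CPM gave 429 between siliques and, for TEs, 7, 4 and 2 in Col, between hybrids and in the interaction. DESeq2 gave 614 for the interaction, 1137 beyond both parents in Col and 0 TEs in each comparison. Unique sequence only gave 567 between siliques. Factors from the TE table gave 5, 27 and 0 TEs in C24, between hybrids and in the interaction.

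List tests passed 31 times in the fit as planned, 0 with an estimated correlation in camera, 27 over unique sequence only and 32 with a replicate block. Same-numbered libraries deviated together in the A. thaliana controls (correlation of deviations 0.69), and C24 hybrids deviated with Col controls (0.38) and C24 controls (0.35). Other pairs with seeds gave -0.11 to 0.1 and siliques -0.4, so the numbers were not taken to pair the libraries. With a replicate block the counts were 3661 for Col, 6678 for C24, 2141 between hybrids and 344 for the interaction. Beyond both parents, part of the excess over independent lists may come from the shared hybrid libraries. The share of genes with the same sign in both comparisons was 58.1% in Col and 53.5% in C24, against 64.8 and 64.6% in simulated unchanged groups. Alternatives with the control records titled single, and a fit over all 7 groups for TEs, were not run, because the tables hold sums of those records and the TE table has only 4 groups.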

Other observations

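Of the tests in this part, none was chosen after its result was seen. Among the largest differences between Col and C24 were loci with few or no reads in the other accession. In hybrid seeds ARGAH2, an arginase gene, stood at 16.5 ± 1.78 CPM in Col and had no read in C24, at least 64.0-fold higher. LCR48, of the cysteine-rich peptide family, was higher in Col hybrids by a ratio of 3310 (95% interval 916 to 27300), and in control seeds it was at least 454-fold higher. In the other direction AT4G07965 was lower in Col hybrid seeds by a ratio of 302 (53.7 to 12000), at least 60.0-fold lower in Col control seeds and at least 106-fold lower in Col siliques. AT3G44215 was at least 113-fold lower in Col hybrid seeds and at least 195-fold lower in Col siliques.

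In the fruit, CYP83A1, a gene of glucosinolate synthesis, had 77.1 ± 20.7 CPM in C24 hybrid siliques and no read in the seeds, at least 285-fold higher. CORI3, a gene induced by coronatine, was at least 188-fold higher in Col and at least 102-fold higher in C24 siliques. The meristem gene STM had 19.6 ± 2.34 CPM in Col siliques and 0.511 ± 0.382 CPM in seeds (5.07 ± 0.39, adjusted p = 2.98e-05 in edgeR). In A. arenosa seeds the thionin gene THI2.1 had no read and was at least 1910-fold lower than in Col and at least 455-fold lower than in C24 control seeds. AGP23, an arabinogalactan gene of pollen, stood at 1100 ± 1330 CPM in A. arenosa.

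Some transcripts of hybrid seeds may come from the A. arenosa genome. Of 310 genes with a mean under 0.5 CPM over the 4 A. thaliana control libraries and at least 5 CPM in both A. arenosa libraries, 7 reached 1 CPM in all 4 hybrid seed libraries, or 2.26% (95% exact interval 0.91 to 4.6). Of 10556 genes as low in those controls with at most 3 reads in A. arenosa, 25 did so, or 0.24% (0.15 to 0.35; Fisher's exact test, two-sided, p = 2.62e-05). The 7 were AT5G25415, EXPA22 (48.1% not unique), AT1G36240, MIOX5, AT4G04145, AT3G62710 and PnsL2. Per total gene reads, AT1G36240 had 261 ± 26.1 CPM in A. arenosa and 29.3 ± 1.61 and 44.5 ± 10.5 in Col and C24 hybrids. AT5G25415 (11.1 ± 4.93, 55.7 ± 7.88 and 70.4 ± 22.5) and EXPA22 (24.8 ± 13.4, 75.9 ± 20.4 and 57.5 ± 6.98) lay above the A. arenosa control, which that parent's level alone would not give. The other 4 lay below it in both hybrids. The comparison genes were low in all controls, so tissue left on seeds could also give this excess. No sequence difference was examined, and an A. arenosa origin stays a hypothesis resting on 7 genes.

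The A. arenosa control libraries may hold RNA of other tissues. The pollen list had a median log2 fold change of 7.37 against the Col control, where 9 of its 13 genes had passed the filter among seeds of A. thaliana mothers, and VGD1 stood at 3170 ± 3390 CPM. The photosynthesis list, all 20 of which passed there too, had a median of 3.43, and plastid loci took 6.13 and 2.36% of the gene reads. A weaker match of A. arenosa reads to the A. thaliana genome lowers counts, so it was not expected to raise a list. The pollen median lay 7.62 above the median of all genes, but that value is the pattern itself and no separate test. Whether a weaker match lies behind the genes called lower in A. arenosa was not tested. Pollen and green tissue in the samples, and a difference between the species, stay open.

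Among ribosomal RNA loci, AT2G01020, AT3G41979, ATCG00920 and ATCG01210 had reads in hybrid seeds and none in any control, A. arenosa or silique library. AT2G01010 had between 21375 and 37939 reads in hybrid seeds, between 2 and 19 in the controls and A. arenosa, and between 6 and 51 in siliques. AT3G41768 had reads in every library, 6768 to 60390 in the A. thaliana controls, 10275 and 6763 in A. arenosa, 44426 to 85696 in hybrid seeds and 7609 to 74823 in siliques. The treatment of reads with several matches was not given in the sources used here, so all these values are uncertain.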
